A study of Mus musculus with 9 samples.

How the data were processed

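RNA from 9 cell lines of murine 4T1 mammary carcinoma was measured on 9 Affymetrix Mouse Gene ST arrays, 1 per line: 3 lines from primary tumors, 3 from lung metastases and 3 from brain metastases. Per the labels, the tumors came from 9 separate mice, the lines were frozen as separate lines, and all were thawed, cultured and extracted together, so no batch is recorded. The deposited values are log2 intensities made with RMA, per the submitters' processing notes, which comprises background correction, quantile normalization between arrays and a summary per probe set. The notes do not name the log base, and the range of the values is that of log2. The software version of RMA and a genome build are not given in the sources used here. The table held 35557 probe sets for all 9 arrays. The number of arrays limits the precision, and no depth or detection p is given. The median level of the probe sets with no symbol was 4.21, and a single gene with a group mean below it is described by its levels without a fold or log2 change, since it may lie at background.

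Probe sets were named through the platform's annotation. Of these, 21789 had exactly 1 gene symbol, 1621 had several and 12147 had none, and genes were named only from the first kind. For the 999 genes with more than 1 probe set, the one with the highest mean over all 9 arrays was used, which left 19938 genes. Of 115 named genes, 5 had another probe set, and in 1, Sema4d, the other probe set had the opposite sign (log2 change in brain against lung lines 0.61 in the brighter and -0.15 in the dimmer probe set). Adjusted over all 35557 probe sets, the other probe set did not pass in any of the 5. A reference gene table of assembly GRCm38.p6 held 19856 of the genes and was used only for names, older symbols and the order of neighbouring genes.

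Each gene was tested with limma (lmFit and eBayes, two-sided, no intensity trend) in 1 model of all 9 arrays with a coefficient per origin, 6 residual degrees of freedom and 3.72 prior degrees of freedom. The contrasts were brain against primary, lung against primary and brain against lung lines, with an F test over the 3 origins. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 19938 genes. Errors after ± are standard errors of the model unless marked SD. An exact permutation test of 3 lines against 3 cannot give a p under 0.1, so none is given for single genes.

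There were 32 gene lists and 11 lists of cell type markers, written with the tests, the alternatives and the rule for naming genes before the data were examined. Of 1107 different symbols in them, 1034 matched a tested gene, 11 of them through an older symbol. The rest are not analysed here. A symbol that is now the symbol of a gene was never read as an older name of another gene. An earlier match without this rule had taken some symbols for other genes and was replaced after its results had been seen. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 96 tests of the gene lists, and separately over the 33 tests of the marker lists. Camera compares a list with the other genes, and the preset correlation can understate how far a list's genes move together, so the p with a correlation estimated per list is given beside it. Limma's fry, which asks whether a list's genes move on balance in 1 direction, was an alternative. Counts adjusted over the list alone use only that list's genes.

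The rule named, per contrast, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, without predicted, olfactory, histone and small RNA genes. It added up to 4 called members per list with the largest changes, up to 2 members for a list with none, and the 10 genes with the smallest p where fewer than 5 passed. From that set, the genes whose call held without any 1 line were mostly chosen for the text, a choice made after these fits were seen, and the others are given as counts. Members of the YAP target set and genes of the run between Insr and Galnt7 fall outside the rule and were chosen after their values were seen.

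The labels number the mice 1 to 3 in each origin, although the mice are separate animals. Deviations of same-numbered lines from their group means correlated across genes at 0.284, 0.130 and 0.241 between brain and lung lines, each above 0.1, so a model with the mouse number as a block is given for brain against lung lines where it changes a call. The pairing comes from the data alone, and what the number stands for is not stated.

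The alternatives were quantile normalization again, centring each array on its median, leaving out the dimmest 33.3% of genes, an intensity trend with a robust prior, array weights, the replicate block, leaving out each line in turn, every probe set as its own feature (for lists, the mean of a gene's probe sets), stricter thresholds, a model of only the 6 arrays compared and a linear model without moderation of the variances. The procedure was tested on simulated data for brain against primary lines over 19938 genes. It recovered 58 of 67 genes changed 1.5-fold (86.6%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 4-fold, with 7 false calls among the unchanged genes, and 0 of 93 tests of unchanged lists were called. The noise of each gene was drawn with its moderated variance, so the recovered shares may be higher than the data would give. The simulated genes varied independently and the unchanged lists held random genes. The simulation therefore does not show how often lists are called falsely when their genes move together. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for figures.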

Results

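Gene expression was measured in 9 cell lines grown from tumors of 4T1 cells, a mouse mammary carcinoma line that spreads to distant organs. Each line came from a different mouse and was measured on 1 array. Of these lines, 3 came from primary tumors (4T1-T2), 3 from lung metastases (4T1-LM2) and 3 from brain metastases (4T1-BM2), and they are called primary, lung and brain lines here, numbered as the mice of each origin. The labels give the lines of an origin a common name and do not state what it marks, and if the 3 lines shared a selected ancestor they would count as fewer than 3 independent samples in every comparison. All were grown and extracted side by side, so the values describe cells in culture and not tumors in the animal. Each array gave 35557 log2 values, with medians between 5.06 and 5.19, and the number of arrays limits the precision. The spread of each array around the gene medians (the interquartile range of relative log expression) was widest in brain line 3, at 0.178, and lung line 1, at 0.164, against 0.0886 to 0.126 in the other lines.

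Origin separated the brain lines from the rest. The first principal component held 37.5% of the variance and placed the brain lines at 14.0, 17.7 and 27.3, while the lung lines lay between -12.1 and -5.82 and the primary lines between -14.8 and -8.42. The limma F test over the 3 origins called 470 of 19938 genes. That count was 210, 160 and 181 without brain lines 1, 2 and 3, 213 and 288 without lung lines 2 and 3, and 288 and 262 without primary lines 1 and 2.

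**Figure D1:**
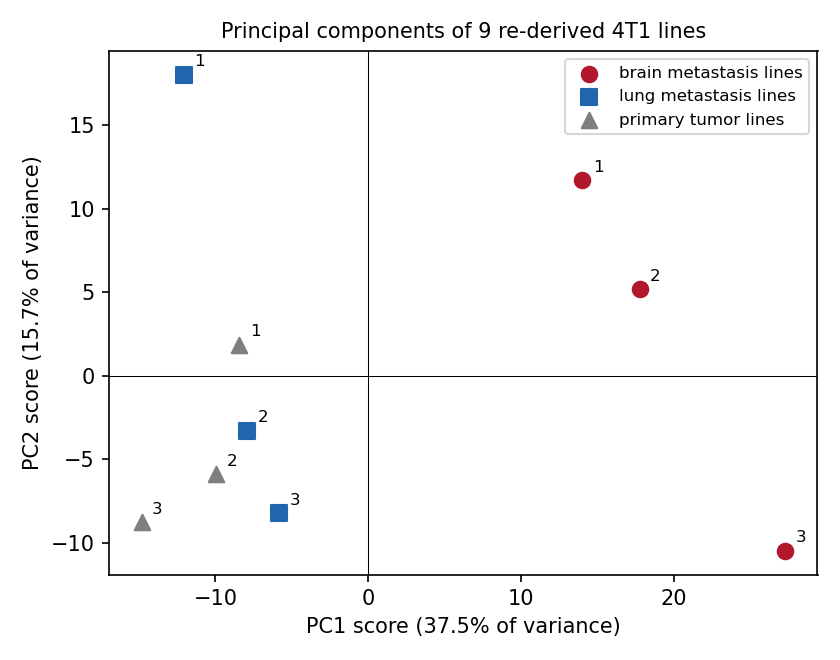
Principal components of the 9 lines over all genes tested, with 1 point per line, colored by origin and numbered by mouse; the axes are component scores, with 37.5% of the variance on the first and 15.7% on the second. The 3 brain lines lie above 0 on the first component and the 6 other lines below 0.

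How brain lines differ from primary lines is the first comparison. In brain lines, Gatm, which encodes the enzyme of the first step of creatine synthesis, was 8.04-fold higher (log2 change 3.01 ± 0.34, SE, 3 lines per origin, limma adjusted p = 0.00269). Ccnd2, which encodes the cell cycle regulator cyclin D2, was 7.28-fold higher (2.86 ± 0.21, adjusted p = 7.8e-04), and Ccn2, a secreted matrix-associated protein also called CTGF, was 4.76-fold higher (2.25 ± 0.16, adjusted p = 7.8e-04). The largest fall was in Slc14a1, a urea transporter, which was 9.14-fold lower (-3.19 ± 0.23, adjusted p = 7.8e-04). Ptges, which encodes a prostaglandin E synthase, was 4.25-fold lower (-2.09 ± 0.19, adjusted p = 0.0013), and Dll4, a Notch ligand, 4.14-fold lower (-2.05 ± 0.20, adjusted p = 0.00158). Further rises included Moxd1 (6.80-fold), the calcium-binding annexin Anxa8 (4.26-fold), Podnl1 (4.11-fold), the G protein regulator Rgs16 (3.85-fold), the stress response gene Gadd45b (3.64-fold) and Dynap (3.50-fold). Further falls included the arrestin family member Arrdc3 (3.88-fold) and Dapk1, a death-associated kinase (3.54-fold). Akip1 fell from a mean log2 level of 5.65 to 3.74, which is below the median of the unnamed probe sets (4.21), so no change is given. Each gene named so far in this paragraph kept its call when any 1 of the 9 lines was left out. Mmp3, which encodes the protease stromelysin, was 4.70-fold lower (adjusted p = 0.0145), a call lost without primary line 2 (0.0639), with every probe set (0.0621) and with only the 6 arrays compared (0.0861). The other falls among the 12 largest that were lost when a line was left out were B4galt6 (without brain line 2, 0.0508, or 3, 0.0539), Mgst1 (without primary line 1, 0.0694, or 2, 0.0706) and Gpnmb (without primary line 1, 0.0516).

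In all, 624 of 19938 genes passed, 311 higher and 313 lower in brain lines, and 117 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3146 genes, where chance gives 996.9. The 3 brain and 3 primary lines did not overlap in 3555 genes, which is 17.8% where chance gives 10%, and all 624 called genes were among these. The balance of rises and falls depended on scaling: with each array centred on its median the split was 459 higher and 218 lower. The count was 338 and 413 without brain lines 2 and 3, and 319, 273 and 366 without primary lines 1, 2 and 3.

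**Figure D2:**
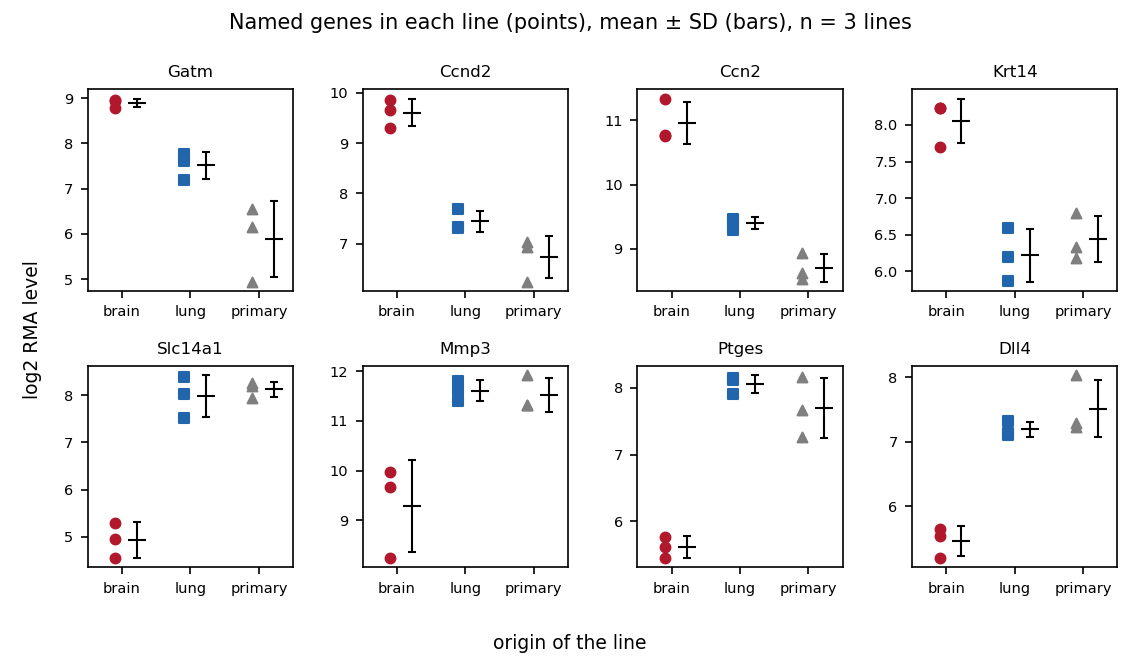
Log2 RMA level of 8 genes in each line, by origin, with 1 point per line and the mean with its SD as bars. Gatm, Ccnd2, Ccn2 and Krt14 lie higher in all 3 brain lines than in the 3 primary lines, and Slc14a1, Mmp3, Ptges and Dll4 lie lower.

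Genes of cholesterol synthesis and uptake were higher in brain than in primary lines as a group: 6 of 21 measured members rose, 0 fell and 15 did not pass, and 14 rose when adjusted over the list alone. The list's median log2 change was 0.53 (limma camera with its preset correlation, adjusted p = 2.5e-10, and adjusted p = 0.574 with an estimated correlation). Hsd17b7, a reductase of the sterol pathway, rose by 0.94 ± 0.14 on the log2 scale (SE, adjusted p = 0.00979). Relative to the mean of the primary lines, the mean of the list was 0.53, 0.55 and 0.35 in the brain lines and -0.10, -0.15 and 0.25 in the primary lines. Genes of epithelial junctions and identity were higher as well, with 7 of 33 rising, 26 not passing and a median of 0.21 (adjusted p = 6.8e-06, and adjusted p = 0.415 with an estimated correlation). Of these, 14 rose when adjusted over the list alone. Among them Cgn, which encodes the tight junction protein cingulin, rose by 1.36 ± 0.18. Of 26 mesenchymal genes 1 fell, the transcription factor gene Foxc2 (-1.07 ± 0.08, adjusted p = 8.7e-04), and 5 fell when adjusted over the list alone. That list's median was -0.11 (adjusted p = 0.0352, and adjusted p = 0.626 with an estimated correlation), and its call was lost without brain line 1 (0.0776), brain line 3 (0.114) or primary line 2 (0.0772) and without the dimmest genes (0.105).

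Hypoxia response genes were also higher in brain than in primary lines, with 6 of 30 rising and 24 not passing (median log2 change 0.12, adjusted p = 0.00581, and adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone, 8 rose and 2 fell. The carbonic anhydrase genes Car9 (1.42 ± 0.17) and Car12 (1.41 ± 0.13) and the mitochondrial gene Higd1a (0.77 ± 0.11, and 0.34 in its other, dimmer probe set, adjusted p = 0.220) were among those that rose. For oxidative phosphorylation none of 45 members passed and 4 rose when adjusted over the list alone, with a median of 0.11 (adjusted p = 3.9e-04, and adjusted p = 0.644 with an estimated correlation). For glycolysis 2 of 19 rose, Hk2 (hexokinase) by 0.48 ± 0.11 and Tpi1 (triose phosphate isomerase) by 0.34 ± 0.07, and the list's median was 0.10 (adjusted p = 0.0437, and adjusted p = 0.577 with an estimated correlation). In the glycolysis list 6 rose and 1 fell when adjusted over the list alone. The glycolysis call was lost without brain line 2 (0.176), primary line 1 (0.105), primary line 2 (0.132), lung line 1 (0.0784), lung line 2 (0.0504) or lung line 3 (0.0502). It was also lost with quantile normalization again (0.139), with median centring (0.0765), without the dimmest genes (0.0848) and with every probe set (0.0636). Hk2 and Tpi1 each passed only when brain line 1 or lung line 1 was the line left out, with adjusted p up to 0.147 without primary line 2 for Hk2 and 0.119 for Tpi1. Neither passed with every probe set (0.119 and 0.0843) or with only the 6 arrays compared (0.108 and 0.104), and Tpi1 did not with quantile normalization again (0.0621).

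Oxidative stress genes were lower in brain than in primary lines: 2 of 37 fell and 35 did not pass (median log2 change -0.13, adjusted p = 8.2e-04, and adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, 8 fell and 1 rose. Slc7a11, the cystine transporter gene, fell (-1.43 ± 0.17, adjusted p = 0.00386). Targets of TGF-beta and BMP signaling went both ways, with 6 of 30 rising and 2 falling, and with 11 rising and 3 falling when adjusted over the list alone. The matrix-associated genes Ccn2, Ccn1 (1.45 ± 0.15) and Thbs1 (1.16 ± 0.10) rose, while Id3, an inhibitor of DNA binding induced by BMP, fell (-1.33 ± 0.16). The list's median was 0.07 (adjusted p = 0.0346, and adjusted p = 0.415 with an estimated correlation), and limma's fry test gave adjusted p = 0.0106. The camera call was lost without brain line 2 (0.0980) or lung line 1 (0.05005) and with median centring (0.0968).

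**Figure D3:**
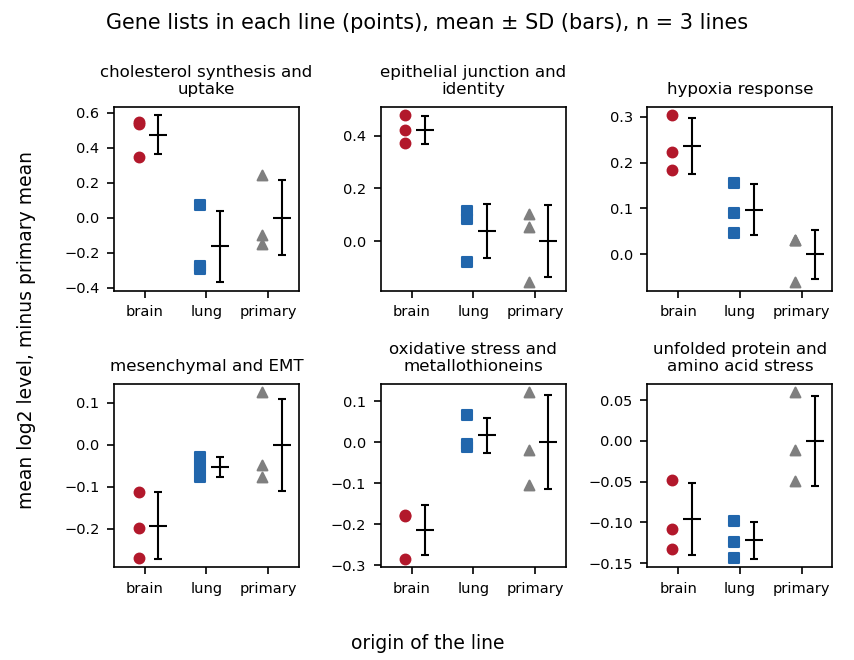
Mean log2 value of 6 gene lists in each line, relative to the mean of the primary lines, with 1 point per line and the mean with its SD as bars. For cholesterol synthesis the brain lines lie at 0.53, 0.55 and 0.35, above the lung lines, which lie between -0.29 and 0.07.

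The other 24 lists were not called in brain against primary lines, with adjusted p from 0.0579 to 0.988. Leaving out a line brought some past the threshold: p53 targets without brain line 1 (higher, 0.0348), the EGFR family list (lower, 0.0141) and axon guidance genes (lower, 0.0463) without brain line 2, fatty acid genes without brain line 3 (higher, 0.0306) and published lung metastasis genes without primary line 3 (lower, 0.0494). Quantile normalization again did so for p53 targets (0.0459) and median centring for the EGFR family list (0.0314). Among basal and keratinocyte genes 4 of 23 rose, or 5 adjusted over the list alone, including the basal keratin gene Krt14 (1.62 ± 0.22, adjusted p = 0.00568). Matrix protease genes went both ways, with 3 of 50 rising and 6 falling, or 5 and 10 adjusted over the list alone, and those that rose included the gelatinase gene Mmp9 (1.52 ± 0.18) and Adam12 (1.86 ± 0.23). Of the collagens 2 rose and 2 fell, or 2 and 3 adjusted over the list alone, and the falls over all genes were in the basement membrane genes Col4a1 (-0.79 ± 0.08) and Col4a2 (-0.74 ± 0.10). Both genes lie, with Dusp4, in a run of neighbouring genes between Insr and Galnt7 that was lower in brain lines. Of the angiogenic factors 4 of 40 rose and 2 fell, or 6 and 5 adjusted over the list alone, with rises in the growth factor gene Pdgfb (1.67 ± 0.23) and the endothelin gene Edn1 (1.20 ± 0.16). Of the Wnt genes 3 of 36 rose, or 3 with 1 falling adjusted over the list alone, among them Wnt7a (1.86 ± 0.29) and Wnt10a (0.82 ± 0.08), and in the Notch list Dll4 fell, as 1 of 25 by either adjustment. The EGFR family list also holds ligands and other genes, such as those of the Dusp, Spry, Spred and Etv groups. Of its 25 genes 2 rose and 3 fell, or 4 and 9 adjusted over the list alone. The falls included Dusp4 (-0.68 ± 0.10) and Etv5 (-0.63 ± 0.10, and -0.67 in its other probe set, adjusted p = 0.156), which are neither receptors of that family nor ligands. Of the genes published for brain metastasis 1 of 24 rose and 1 fell, or 2 and 1 adjusted over the list alone, the fall being Tnfsf10, which encodes the death ligand TRAIL (mean log2 level 4.00 in brain and 5.09 in primary lines, the former below the 4.21 median of the unnamed probe sets). Of those published for lung metastasis 2 of 21 fell, among them Id3, or 1 rose and 3 fell adjusted over the list alone. Laminins and other glycoproteins (5 higher, 0 lower), cytokines (3 and 2), integrins (2 and 1), axon guidance (3 and 5), fatty acid handling (2 and 2), unfolded protein stress (0 and 3), p53 targets (4 and 1), immediate early genes (1 and 1), luminal genes (1 and 0) and synaptic genes (0 and 1) also held members that passed. Adjusted over the list alone, the same counts were 6 and 5 for laminins, 6 and 4 for cytokines, 2 and 2 for integrins, 4 and 13 for axon guidance, 5 and 2 for fatty acids, 0 and 5 for unfolded protein stress, 4 and 1 for p53, 3 and 4 for immediate early, 1 and 1 for luminal and 0 and 1 for synaptic genes. In the gap junction, interferon, MHC class I, MHC class II and cell cycle lists none passed in limma or was called, and over the list alone 1 MHC class II gene rose. Median and mean differed in sign for the cell cycle, MHC class I, laminin, Wnt and synaptic lists, and for Wnt the test was Down while the mean was 0.04.

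Of the 88 called genes that the naming rule gave for this comparison, 46 kept their call in all 9 fits that left out 1 line. Of the 88, 43 lost it with every probe set tested, 40 with only the 6 arrays compared and 75 without moderation of the variances. Of the genes given above as rising or falling, all but Mmp3, B4galt6, Mgst1, Gpnmb, Hk2 and Tpi1 are among the 46.

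Whether lung lines differ from primary lines is the second comparison. No gene passed in limma, where the smallest adjusted p was 0.975. Among the 10 genes with the smallest p, all with an adjusted p of 0.975, Gatm had a log2 change of 1.63 ± 0.34 (SE, 3 lines per origin). Padi3 (-1.15 ± 0.20), Dapk1 (-1.12 ± 0.22), Plscr2 (1.09 ± 0.23), the chemokine gene Ccl2 (0.80 ± 0.16), Sh2d1b1 (0.61 ± 0.13), and Tmem185b (-0.47 ± 0.08) were also among them. The other 3 had a group mean below the 4.21 median of the unnamed probe sets, so their mean log2 levels in lung and primary lines are given: 3.24 and 4.89 for the zinc finger gene Zfp979, 4.06 and 3.69 for Doc2b, and 4.22 and 3.84 for Sectm1a. At an unadjusted p under 0.05 there were 946 genes where chance gives 996.9, and the groups did not overlap in 1737 genes, which is 8.71% where chance gives 10%. The same model without moderation of the variances called 1 gene, B430212C06Rik, with mean levels of 3.47 in lung and 3.42 in primary lines.

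Small shifts of whole lists were called between lung and primary lines, in each of which 0 members passed over all genes. Genes of the unfolded protein and amino acid stress response were lower, with a median log2 change of -0.10 over 32 genes (camera adjusted p = 4.3e-06, and adjusted p = 0.415 with an estimated correlation). The largest values in that list were those of Slc7a11 (-0.48 ± 0.17) and Chac1 (-0.38 ± 0.18). This was the only one of 9 called lists that kept its call when any 1 line was left out. Over all 3 comparisons 24 of 96 list tests were called, while divisions of the 9 lines that mixed brain with other lines gave a median of 11 calls. Cholesterol synthesis was lower (median -0.15, adjusted p = 3.9e-04, and adjusted p = 0.760 with an estimated correlation), a call lost without lung line 1 (0.0753), lung line 2 (0.0717) or primary line 3 (0.394). Immediate early genes were lower (-0.12, adjusted p = 0.00124, and adjusted p = 0.644 with an estimated correlation), lost without lung line 1 (0.0539) or primary line 3 (0.150). Cell cycle genes were higher (0.05, adjusted p = 0.0152, and adjusted p = 0.713 with an estimated correlation), lost without lung line 2 (0.176) or primary line 3 (0.643). Hypoxia genes were higher (0.12, adjusted p = 0.0346, and adjusted p = 0.576 with an estimated correlation), lost without lung line 3 (0.205) or primary line 1 (0.171). Genes listed as p53 targets were lower (-0.04, adjusted p = 0.0347, and adjusted p = 0.537 with an estimated correlation), with 2 lower when adjusted over the list alone, Trp53inp1 (-0.65 ± 0.16) and Mdm2 (-0.29 ± 0.07) having the largest values. That call was lost without lung line 1 (0.199), lung line 3 (0.0606) or primary line 2 (0.141), with quantile normalization again (0.0520) and with array weights (0.0769).

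Glycolysis genes were higher in lung than in primary lines (median log2 change 0.11, adjusted p = 0.0357, and adjusted p = 0.576 with an estimated correlation), a call lost without lung line 1 (0.113), 2 (0.0617) or 3 (0.0751) or primary line 1 (0.110) or 2 (0.212). Fatty acid genes were higher (0.08, adjusted p = 0.0357, and adjusted p = 0.574 with an estimated correlation), with 2 higher when adjusted over the list alone, and the call was lost without lung line 1 (0.0753), 2 (0.0556) or 3 (0.169) or primary line 2 (0.122) or 3 (0.0621). Oxidative phosphorylation genes were higher (0.04, adjusted p = 0.0403, and adjusted p = 0.822 with an estimated correlation), lost without lung line 2 (0.174) or 3 (0.608) or primary line 1 (0.189) or 3 (0.150) and with median centring (0.0527). The other 23 lists had adjusted p from 0.0795 to 1.00. Of these, the interferon list was called higher without lung line 1 (0.0174) or primary line 1 (0.0423), collagens higher without lung line 2 (0.0372) or 3 (0.00227), and published lung metastasis genes lower without primary line 1 (0.0464) or 3 (0.0186). In 4 of them, those of MHC class I, laminins, matrix proteases and Wnt genes, the median was above 0 and the test Down. Adjusted over the list alone, 1 cytokine gene and 1 gene of the TGF-beta list rose, and no other uncalled list held such a gene.

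How the metastasis lines of both sites differ is the third comparison. In brain against lung lines, Slc14a1 was 8.24-fold lower (log2 change -3.04 ± 0.23, SE, 3 lines per origin, limma adjusted p = 0.00187) and Ptges 5.45-fold lower (-2.45 ± 0.19, adjusted p = 0.00187). Angpt1, an angiopoietin gene, fell from a mean log2 level of 5.89 to 3.89 (adjusted p = 0.00633). Ccnd2 was 4.46-fold higher (2.16 ± 0.21, adjusted p = 0.00315), Podnl1 4.02-fold higher (2.01 ± 0.18, adjusted p = 0.00203) and Krt14 3.57-fold higher (1.84 ± 0.22, adjusted p = 0.00631). Gadd45b was 3.39-fold and Ccn2 2.93-fold higher, while Dll4 was 3.31-fold and the efflux transporter gene Abcc3 3.06-fold lower. Zfp979 rose from 3.24 to 5.23 and Akip1 fell from 5.58 to 3.74. The lower level of Angpt1, Zfp979 and Akip1 is below the 4.21 median of the unnamed probe sets, so no change is given for them. Each of these kept its call when any 1 of the 9 lines was left out. The small GTPase gene Rab25 had the largest rise, 4.96-fold (adjusted p = 0.0221), but lost its call without brain line 1 (0.0691) or 2 (0.0756) or lung line 1 (0.0880), 2 (0.0957) or 3 (0.0736), and with every probe set (0.0879).

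In all, 395 genes passed, 182 higher and 213 lower in brain lines, and 90 changed at least 2-fold. At an unadjusted p under 0.05 there were 2971 genes where chance gives 996.9. The groups did not overlap in 3368 genes, which is 16.9% where chance gives 10%, and all 395 called genes were among these. With each array centred on its median the split was 296 higher and 146 lower. The count was 208 and 217 without brain lines 2 and 3, and 136, 69 and 142 without lung lines 1, 2 and 3. Of the 71 called genes that the naming rule gave for this comparison, 25 kept their call in all 9 fits that left out 1 line. Of the 71, 45 lost it with every probe set tested, 42 with only the 6 arrays compared and 71 without moderation of the variances.

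Cholesterol genes stood furthest apart between brain and lung lines, with 10 of 21 rising, 11 not passing, 17 rising when adjusted over the list alone and a median log2 change of 0.71 (camera adjusted p = 2.4e-16, and adjusted p = 0.537 with an estimated correlation). Hsd17b7 rose by 1.31 ± 0.14. The lanosterol synthase gene Lss rose by 1.04 ± 0.15 (adjusted p = 0.0101), a call lost without lung line 2 (0.0633), with every probe set (0.0514) and with only the 6 arrays compared (0.0507). Epithelial genes were higher, with 6 of 33 rising, 27 not passing, 14 rising when adjusted over the list alone and a median of 0.37 (adjusted p = 6.6e-06, and adjusted p = 0.415 with an estimated correlation). Genes listed as p53 targets were higher, with 4 of 22 rising, 18 not passing, 7 rising when adjusted over the list alone and a median of 0.19 (adjusted p = 5.1e-04, adjusted p = 0.415 with an estimated correlation, and 0.0324 with fry). Whether p53 itself drives these genes was not tested in any comparison. The antiproliferative gene Btg2 rose by 0.61 ± 0.07 (adjusted p = 0.00499). Oxidative stress genes were lower, with 4 of 37 falling, 33 not passing, 7 falling when adjusted over the list alone and a median of -0.14 (adjusted p = 3.6e-04, and adjusted p = 0.574 with an estimated correlation). The quinone reductase gene Nqo1 fell (-1.28 ± 0.19, adjusted p = 0.0128), a call lost without lung line 1 (0.0590) or 2 (0.0743) and with every probe set (0.0607).

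Collagens were lower in brain than in lung lines, with 2 of 41 falling, Col4a1 (-0.70 ± 0.08) and Col4a2 (-0.79 ± 0.10), both in the run between Insr and Galnt7, and with 1 higher and 3 lower when adjusted over the list alone. The median was -0.09 (adjusted p = 0.0142, and adjusted p = 0.822 with an estimated correlation), and the call was lost without brain line 3 (0.0590) or lung line 1 (0.654), with quantile normalization again (0.199) and with array weights (0.187). TGF-beta targets went both ways, with 5 of 30 rising and 2 falling, 9 rising and 3 falling when adjusted over the list alone, and a median of 0.05 (adjusted p = 0.0495, adjusted p = 0.475 with an estimated correlation, and 0.0386 with fry). Ccn1 rose by 1.29 ± 0.15 and Id3 fell (-1.29 ± 0.16). The camera call of that list was lost without brain line 1 (0.0805) or 2 (0.148), lung line 1 (0.0753), 2 (0.0504) or 3 (0.168), or primary line 2 (0.0594) or 3 (0.0572). It was also lost with quantile normalization again (0.105), median centring (0.190), without the dimmest genes (0.0848), with every probe set (0.0515) and with the replicate block (0.0840). For oxidative phosphorylation 0 of 45 members passed or did so over the list alone, with a median of 0.04 (adjusted p = 0.0446, and adjusted p = 0.822 with an estimated correlation). That call was lost without brain line 1 (0.132) or 3 (0.143), lung line 1 (0.501), or primary line 1 (0.0510), 2 (0.0551) or 3 (0.0621), without the dimmest genes (0.112), with array weights (0.274) and with the replicate block (0.0840). Quantile normalization again turned its median to -8.7e-04 (adjusted p = 0.798).

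The other 25 lists were not called between brain and lung lines, with adjusted p from 0.0713 to 0.988. Of these, hypoxia genes were called higher without brain line 1 (0.0197), and lower calls came for mesenchymal genes (0.0463) and the EGFR family list (0.0169) without brain line 2, for interferon genes without brain line 3 (0.0222) or lung line 1 (0.0109), and for cell cycle genes with quantile normalization again (0.00198). Higher and lower members numbered 3 and 3 for matrix proteases, 3 and 1 for angiogenic factors, 3 and 0 for hypoxia, 2 and 2 for cytokines, 1 and 4 for axon guidance, 1 and 3 for fatty acids and 2 and 0 for each of the basal, laminin and Wnt lists. Adjusted over the list alone, these were 3 and 5, 7 and 3, 7 and 1, 4 and 7, 2 and 6, 3 and 4, then 4 and 0 for basal, 2 and 0 for laminin and 3 and 0 for Wnt genes. Members that passed included Foxc2 (-0.93 ± 0.08), the macrophage growth factor gene Csf1 (0.61 ± 0.08), Thbs1 (0.94 ± 0.10), Car12 (1.06 ± 0.13), Wnt10a (0.73 ± 0.08) and the semaphorin gene Sema4c (-1.23 ± 0.17). Sema4c kept its call without any 1 line, as the others did, but had an adjusted p of 0.0514 with every probe set and 0.0552 with only the 6 arrays compared. In the laminin, angiogenic, glycolysis, immediate early, MHC class I, MHC class II and published brain metastasis lists the test was Up while the median was below 0, for fatty acid genes the test was Up and the mean -0.01, and for Wnt genes the test was Down and the mean 0.02.

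Of the genes called in either brain comparison, 298 were called in both, all in the same direction, against 12.4 for independent lists. Both comparisons share the brain arrays, so part of that overlap may come from them. A further 326 were called only against primary lines and 97 only against lung lines. No gene was called in the same direction in both brain and lung lines against primary lines, a count fixed by the 0 calls of limma in lung lines, which therefore says nothing about shared change. Over all genes the brain and lung changes against primary lines had a covariance of 0.0114. It was 0.0063 (0.0058 to 0.0068) in 100 simulations of unchanged brain and lung groups against a common simulated primary group, a difference of 0.0051. Their correlation across genes, which are not independent replicates, was 0.394 against 0.500 in the simulations, and 62.9% had the same sign against 66.7%. The simulated values already hold what sharing the primary arrays gives without any change. They were drawn independently for each gene and array, so they leave out the correlation of same-numbered brain and lung lines and that between genes. The simulated range is therefore too narrow a measure, and no shared change is read from the difference. Dividing the 3 primary arrays between both comparisons would leave a single primary array for a comparison, and this was not done.

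Markers of other cell types gave no call. None of the 11 lists (neurons, astrocytes, oligodendrocytes, microglia and macrophages, neutrophils, lymphocytes, endothelial cells, fibroblasts and pericytes, lung epithelium, erythroid cells and adipocytes) was called by camera in any comparison, with adjusted p from 0.543 to 0.971. At an unadjusted p under 0.05 there were 3 of 33 tests, and with an estimated correlation or with fry 0 were called. Median, mean or test differed in sign for microglia in both comparisons with primary lines, for lymphocytes and erythroid cells in lung against primary lines, for endothelial cells and erythroid cells in brain against lung lines and for lung epithelium in both comparisons with lung lines. Of their members the oligodendrocyte marker Cnp passed, lower in brain lines than in primary lines (-0.57 ± 0.09, adjusted p = 0.0128) and than in lung lines (-0.47 ± 0.09, adjusted p = 0.0362). The first call was lost with only the 6 arrays compared (0.0591). The second was lost without brain line 1 (0.0624), 2 (0.0826) or 3 (0.115), lung line 1 (0.0764), 2 (0.129) or 3 (0.124) or primary line 1 (0.0688), and with median centring (0.0656), every probe set (0.104) or only the 6 arrays compared (0.0617). In the brain and primary lines the mean log2 level was 6.41 and 6.17 for the myelin gene Mbp, 4.49 and 4.50 for the neuronal gene Snap25, 4.42 and 4.47 for the astrocyte gene Gfap, and 7.75 and 7.12 for the astrocyte and glycolysis gene Aldoc, whose log2 change of 0.64 was the largest rise and did not pass (adjusted p = 0.203).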

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

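The test that picked genes with brain and lung lines on opposite sides of the primary lines was set after the calls were seen, as were the use of an interval around the share of neighbouring calls (the limit of 33.3% itself was set earlier) and the bounds and tests of the run between Insr and Galnt7.

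In 5 of the named genes all brain lines lay on one side of the primary lines and all lung lines on the other, and the difference between brain and lung lines passed in limma. These genes were Hhip, an inhibitor of hedgehog signaling (brain minus lung -1.78, adjusted p = 0.00946), the p53 target Btg2 (0.61, adjusted p = 0.00499), the glutathione genes Gstp1 (-0.57, adjusted p = 0.0221) and Gsr (-0.34, adjusted p = 0.0305), and the semaphorin gene Sema4d (0.61, adjusted p = 0.0101). The other, dimmer probe set of Sema4d had the opposite sign between brain and lung lines (-0.15, limma adjusted p = 0.828). Brain against primary lines also passed for Hhip (-1.47, adjusted p = 0.0134), Btg2 (0.50, adjusted p = 0.00568) and Sema4d (0.40, adjusted p = 0.0371), but not for Gstp1 (0.128) or Gsr (0.0960). The lung change against primary lines had an adjusted p of 0.975 in each of the 5. Of the 395 genes called between brain and lung lines, 48 had this arrangement. Its share over all genes was not counted. Picking genes for the difference between brain and lung lines favours it, so the number does not show opposite changes. Btg2 kept its call without any 1 line, while the call was lost without lung line 2 for Hhip (0.0504) and Sema4d (0.0605). For Gstp1 it was lost without brain line 2 (0.0605) or lung line 1 (0.0846), 2 (0.101) or 3 (0.0544). For Gsr it was lost without brain line 2 (0.0776) or 3 (0.0899), lung line 1 (0.0802), 2 (0.127) or 3 (0.0774), or primary line 1 (0.0532) or 2 (0.0568), and with median centring (0.0778).

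Probe sets without exactly 1 gene symbol, which no comparison uses, also held calls between brain and primary lines. When all 35557 probe sets were tested together, 246 were called and 25 of these had no symbol (17) or several (8), with 8 higher and 17 lower in brain lines. For brain against lung lines 16 such probe sets were called, and for lung against primary lines 0 in limma. Fitted among themselves, these 13768 probe sets gave 0 calls for brain against primary lines in limma, with a smallest adjusted p of 0.133 and 950 at an unadjusted p under 0.05.

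The first pattern weighed is the number of genes that set brain lines apart from primary lines. A single brain line does not carry it, since leaving out each in turn left at least 338 called genes. Another scaling did not end it, since the lower count of both scalings tried was 677, with median centring, which kept 528 of the 624 calls. The deposited values were already quantile normalized, so these scalings cannot exclude that first normalization as a source of calls. Brain cells left in the cultures would bring their abundant transcripts, yet 0 of 51 markers of 4 brain cell types were called higher in limma, 3 were higher at an unadjusted p under 0.05, and their median log2 change was -0.02, although Aldoc, which glycolysis also uses, was at 0.64 (adjusted p = 0.203). Of the called genes 30.3% (Wilson interval 26.8 to 34.0) had a neighbour called in the same direction, against 14.4% on average and at most 19.1% in permuted gene orders, so changes of whole chromosome blocks may account for part of the calls, while 435 of 624 had no such neighbour. The share lies under the limit of 33.3% that had been set, which by that rule alone goes against blocks as the main source. The interval, added later, includes the limit. It treats called genes as independent, although neighbours count through each other, so it may be too narrow. Blocks and gene by gene regulation therefore cannot be told apart here, and a difference that arose with growth in the brain stays open and untested.

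The second pattern is a run of neighbouring genes from Insr to Galnt7, in which 136 of 151 genes with a mean level above 6 were lower in brain than in primary lines, with a median log2 change of -0.28 and -0.04 in lung lines. Of its 312 tested genes 45 were called lower and 0 higher in limma, which is 7.21% of all calls, so the run alone does not make up the difference between the origins. In 100 permuted gene orders the lowest running median was -0.137, against -0.342 observed, so a random order of genes does not account for it. Permuting removes all correlation between neighbours, which lung against primary lines also held (0.180, at most 0.021 permuted) with 0 called genes. Whether the run exceeds that background was not tested. The medians were -0.30, -0.26 and -0.22 in the brain lines and at lowest -0.09 in the others, a gap of -0.130. The run was bounded where the running median of each brain line lay more than 0.2 from the primary mean, in the same direction. That all 3 lie low follows from this rule, so the gap does not decide whether a single line carries the run. A shared loss of chromosome copies, or a common clone behind the 3 brain lines, is a candidate explanation that expression data cannot decide, and no DNA was measured.

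Other divisions of the lines into groups were counted for each result. For brain against primary lines 1 of 10 divisions of the 6 arrays gave as many called genes, the real one with 624, and the highest other gave 0. For brain against lung lines it was also 1 of 10, with 395 and 0, and for lung against primary lines all 10 of 10 gave the real count of 0. With 10 divisions the share cannot fall under 0.05. For the F test, 1 of 100 divisions of the 9 arrays reached the real count of 470, and the highest other gave 362. The 4 others that keep the 3 brain lines together gave 316 to 362. These 100, the real one included, were taken from 280 possible divisions. If the lines are independent, a random division of the 9 lines is an unlikely source of the count of 470. The count rests on keeping the brain lines together, and it does not show that all 3 origins differ. For the lists, 2 of 100 divisions reached the real count of 24. The highest other also gave 24 and keeps the 3 brain lines together. The 95 divisions that mix brain with other lines gave 2 to 20 calls of lists, with a median of 11, while the F test called 0 genes in them. Few divisions gave a count as high as 24, but the 4 others that keep the brain lines together gave 17 to 24. The count therefore does not show that lists differ among all 3 origins. Chance cannot be excluded for a single list, since many such calls arise in groups that ignore origin.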

How the results depend on the processing

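The alternatives were planned, but the replicate block, which the main model leaves out, is given because of correlations seen in the data. No named gene with a call changed sign and no called list changed the direction of its test. The median of oxidative phosphorylation in brain against lung lines did turn, to -8.7e-04 with quantile normalization again, and median centring turned the balance of those calls from 182 higher and 213 lower to 296 and 146. Calls of single genes and lists were those most often lost. Across 169 results for named genes, 3037 values under 18 settings comprised 2313 on the same side of the threshold, 724 no longer past it and 0 reversed. For the 24 calls of lists, 313 of 432 values stayed past the threshold, 119 did not and 0 reversed. In 13 other tests of lists a call was gained under some setting, 20 times in all, 2 of them with quantile normalization again, 1 with median centring, 1 with the replicate block and the others without 1 line. Leaving out each line in turn gave 273 to 556 genes for brain against primary lines, 69 to 417 for brain against lung lines and 160 to 370 for the F test, where fewer arrays also lower the power. It gave 16 to 25 calls of lists, 0 genes for lung against primary lines and 0 shared by both metastasis origins. With every probe set as its own feature the counts were 246 for brain against primary lines, 92 for brain against lung lines and 92 for the F test, and more features were then tested. At an adjusted p under 0.01 they were 157, 66 and 81, and with a change of at least 2-fold 117, 90 and 125, as these thresholds are stricter. With only the 6 arrays compared they were 197 and 107, with fewer arrays to estimate the spread. Without moderation of the variances they were 51 and 3, and 1 for lung against primary lines, and the cause was not tested. With a correlation estimated for each list 0 of 96 tests of lists were called by camera, where 8 had an unadjusted p under 0.05, and with fry 3 were called, TGF-beta targets in both brain comparisons and p53 targets in brain against lung lines. The cause was not tested.

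Both other scalings raised the gene counts of the brain comparisons, while calls of lists went from 24 to 21 with each. Quantile normalization again gave 803 genes for brain against primary lines, of which 601 were among the 624, and 525 for brain against lung lines, of which 375 were among the 395. Median centring gave 677, of which 528 were shared, and 442, of which 326 were shared. With the mouse number as a replicate block 839 genes were called for brain against primary lines, 566 for brain against lung lines, 604 by the F test, 0 for lung against primary lines and 0 shared by both metastasis origins, with 21 calls of lists. Pairing by number was not borne out between brain and primary lines (correlations 0.067, -7.4e-04 and -0.044) or between lung and primary lines (0.221, 0.079 and 0.0080). For brain against primary lines the replicate block ended the calls of glycolysis (0.0680), TGF-beta targets (0.0611), Cdh1 (0.0538) and Itgb6 (0.0590). For brain against lung lines it ended those of TGF-beta targets and oxidative phosphorylation (0.0840 each), Cldn7 (0.0594), St14 (0.0625) and Cxcl16 (0.0525), while p53 targets gained a call in brain against primary lines (0.0441). It changed no other call of a named gene or list. The deposited values carry no detection call, so which genes lie above background is unknown, and leaving out the dimmest 33.3% of genes gave 828 and 511 calls.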

Other observations

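The set of YAP targets was chosen after the calls of Ccn1 and Ccn2 were seen, and so were its tests. A test of whether 1 brain line carried the cholesterol shift was run and left out, since the values per line in the report answer it.

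Brain lines also differed in genes that the report counts without values. Among matrix genes Igfbp7, which encodes an insulin-like growth factor binding protein, rose against primary lines by 1.76 ± 0.28 on the log2 scale (SE, 3 lines per origin, limma adjusted p = 0.0115). The angiogenic factor gene Fgfbp1 rose by 2.34 ± 0.35 (adjusted p = 0.0093) and Angpt1 fell from a mean level of 5.65 to 3.89, below the 4.21 median of the unnamed probe sets (adjusted p = 0.00639), while the integrin gene Itga8 fell (-1.69 ± 0.19, adjusted p = 0.00271). The semaphorin gene Sema4c (-1.45 ± 0.17) and the amino acid transporter gene Slc1a4 (-0.59 ± 0.09) fell, and the desaturase family gene Fads3 rose by 0.58 ± 0.09. Each of these kept its call without any 1 line. Fgfbp1 (0.0631), Angpt1 (0.0518) and Fads3 (0.0518) did not pass with only the 6 arrays compared, nor did Igfbp7 with every probe set (0.0534).

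The third pattern weighed is that of Ccn1 and Ccn2, both known targets of the YAP and TEAD transcription factors, which rose in brain lines. Both genes were picked for their calls, and every called gene had its groups apart (624 of 624 and 395 of 395), so the gap of 0.897 between the lowest brain line and the highest other line, which follows from that choice, does not decide whether a single line carries the pattern. Among 20 other published targets 15 were higher in brain than in primary lines, 4 were called higher (Amotl2 0.68, Ankrd1 0.65, F3 0.93 and Nuak2 0.66) and 0 lower in limma, with a median of 0.22. The set had a camera p of 2.1e-04 with the preset correlation and 0.0646 with an estimated correlation, so a wider YAP program may be active in the brain lines, and the stricter test leaves it open. Ccn1 and Ccn2 also respond to TGF-beta, and these data do not separate both inputs.

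Neighbouring genes also moved together in the other comparisons. The correlation of a gene's change with that of its neighbours, across genes, which are not independent replicates, was 0.179 for brain against primary lines, 0.180 for lung against primary lines and 0.206 for brain against lung lines, while in permuted gene orders it was at most 0.025, 0.021 and 0.019.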
